A study of Homo sapiens with 6 samples.

How the data were processed

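RNA was sequenced from 6 sorted samples, which were 3 populations (K18+, K18+K14+ and K18+Vim+) of each of the 2 cell lines HCC70 and MDA-MB-468. Per the labels' protocols, cells were fixed in methanol, stained for the antigens, sorted by flow cytometry, and RNA was recovered with a kit made for fixed tissue. RNA from fixed cells can be broken, and such breaks act differently on long and short transcripts, which FPKM does not correct. Per the submitters' processing notes, TopHat2 was the aligner and GRCh37 the genome build. Per the labels, the HCC70 K18+ and HCC70 K18+Vim+ libraries carry the same index, so they were not pooled in 1 lane. Lanes and batches are not given in the sources used here, and no comparison within a batch could be made. The aligner version, the counting tool and the annotation are not given in the sources used here.

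The deposited table holds FPKM per Entrez Gene ID for the 6 libraries, made by the authors. It has 18807 rows. A floor of 0.1 FPKM and a ceiling of 10000 FPKM are visible in the values. The ceiling was reached by 1 value, SEC61G in the MDA-MB-468 K18+K14+ library, and 2096 genes lay at the floor in all libraries. A gene at the floor is only listed there, since a read count is not given. Whole-read steps were not seen in the low values, so the depth is unknown and no counting interval is given. The 7 rows with a blank value were left out, and for 5 IDs with 2 rows each the row with the higher mean was kept, which left 18795 genes. Of these, 18732 IDs matched a symbol and 63 did not. The reference tables at hand are of another build (GRCh38.p14) than the data. They were used for names and for the order of neighbouring genes, and no coordinates are printed. XIST and Y-linked genes were left out of the named genes.

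Samples were grouped by the populations and cell lines in the labels. For the main test, genes with a mean of at least 1 FPKM over the 6 libraries (12454 genes) were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with population and cell line as terms and all 6 libraries in 1 fit. This leaves 2 residual degrees of freedom. Populations were paired by cell line, since each line gave 1 library per population by the labels. P-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. The comparisons were the 3 pairs of populations and the 2 lines. Log2 ratios per line and fitted differences are on the log2(FPKM + 1) scale, which understates the differences of low genes. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

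A total of 26 gene lists with 743 distinct genes were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. They cover luminal, basal and myoepithelial, mesenchymal, epithelial junction, keratinocyte differentiation, Notch, polarity and division axis, polycomb, stem and progenitor, G1 and S, G2 and M, histone, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal protein, immediate early and stress, interferon, NF-kappaB and cytokine, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, TGF-beta, Wnt, PDGF, FGF and EGF signalling, immune cell, and fibroblast, endothelial and erythroid genes. Of the mitochondrially encoded list 0 of 15 genes were matched in the table, and of the last list 3 genes passed the filter, so that 24 lists were tested with camera (preset correlation 0.01) and again with an estimated correlation and with fry. List medians are relative to the median of all genes of the same comparison and line.

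Genes were named by rule. For each pair of populations these were the genes of the 3 sort antigens, 10 genes per direction and up to 4 members per list. With no gene past the threshold, the 10 were those of the same sign in both lines with the largest value of the smaller of the 2 absolute log2 ratios. For the lines they were the 10 genes per direction with the largest log2 difference among those passed whose libraries did not overlap, and the 4 list members with the largest differences. Genes named outside this rule include KRT4 in K18+K14+ against K18+, TGFB1 in K18+Vim+ against K18+, SMAD4, RB1 and the neighbours of EGFR.

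The fit was tested on simulated data made from the gene means and the spread that limma estimated, with 50 genes changed at each of 4 sizes. In K18+K14+ against K18+, 0, 0, 42 and 48 of 50 genes were recovered at log2 sizes 1, 2, 4 and 6, with 8 false calls. In K18+Vim+ against K18+ the numbers were 0, 0, 41 and 47 with 2 false calls, and for the lines 0, 3, 44 and 50 with 1 false call.

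Alternatives were no block for cell line, only the 4 libraries of the populations compared, pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, quantile normalization, limma without trend, Spearman in place of Pearson correlation and leaving out each library in turn. After the data were seen, a loess correction of each library's log2 values for transcript length was added (99.9% of tested genes had a length). The length was that of the longest transcript of each gene. For the profile along the genome, the median log2 difference between MDA-MB-468 and HCC70 was taken in 230 windows of 50 neighbouring autosomal genes. The median over the windows was then subtracted.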

Results

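Messenger RNA was measured by sequencing in sorted subpopulations of HCC70 and of MDA-MB-468, 2 human lines of basal-like breast cancer. Both lines were derived from tumours that lack hormone receptors and express keratins of the basal layer. Cells were fixed in methanol, stained with antibodies and sorted into 3 populations: cells positive for keratin 18 alone (K18+), for keratin 18 and keratin 14 (K18+K14+), and for keratin 18 and vimentin (K18+Vim+). Keratin 18 marks luminal epithelium, keratin 14 basal epithelium, and vimentin mesenchymal cells. Each population was represented by 1 library from each line, so that the 6 libraries gave n = 2 per population and the lines were the only replicates. The difference between the lines is itself a term of the fit. The spread behind the p-values below is therefore how far the population differences disagree between these 2 lines. It is not the spread between separate cultures of a line. Values are FPKM, a fragment count scaled to transcript length and library size, as deposited. The number of reads behind them is unknown. The median over the 12454 genes tested ranged from 8.12 FPKM in the MDA-MB-468 K18+K14+ library to 11.83 FPKM in the HCC70 K18+ library. The 100 genes with the highest values took 36.3% of the summed FPKM in the MDA-MB-468 K18+K14+ library, 33.5% in the library labelled MDA-MB-468 K18+Vim+, and 22.5% in the HCC70 K18+ library.

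The genes of the sort antigens were compared first, since they bear on the labels. KRT14 (Entrez Gene 3861), which encodes keratin 14, stood at 48.6 FPKM in the HCC70 K18+K14+ library against 15.3 FPKM in the K18+ library, and at 279 against 47.8 FPKM in MDA-MB-468. In the K18+Vim+ libraries KRT14 stood at 5.76 FPKM in HCC70 and 6.42 FPKM in the library labelled MDA-MB-468. VIM (Entrez Gene 7431), which encodes vimentin, stood at 54.8 FPKM in the HCC70 K18+Vim+ library against 13.4 FPKM in the K18+ library. In MDA-MB-468 the same comparison gave 259 against 12.2 FPKM. KRT18 (Entrez Gene 3875), which encodes keratin 18, lay between 158 and 216 FPKM in the 3 HCC70 libraries. In MDA-MB-468 it stood at 464 FPKM in the K18+ library, 569 FPKM in the K18+K14+ library and 67.7 FPKM in the library labelled K18+Vim+. With limma over all genes none of these differences passed the adjusted threshold. The fitted log2 difference of KRT14 between K18+K14+ and K18+ was 2.06 ± 0.60 (SE, n = 2 per population, limma adjusted p = 0.855), and that of VIM between K18+Vim+ and K18+ was 3.13 ± 0.62 (limma adjusted p = 0.863). Without the HCC70 K18+Vim+ library the VIM difference was 4.21, with a limma adjusted p of 0.00241, KRT14 differed by -2.94, with a limma adjusted p of 0.00561, and KRT18, the antigen shared by all 3 populations, differed by -2.80, with a limma adjusted p of 0.0141. In that fit the K18+Vim+ population is the single library labelled MDA-MB-468 K18+Vim+, which stood apart from its line as described below.

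**Figure D1:**
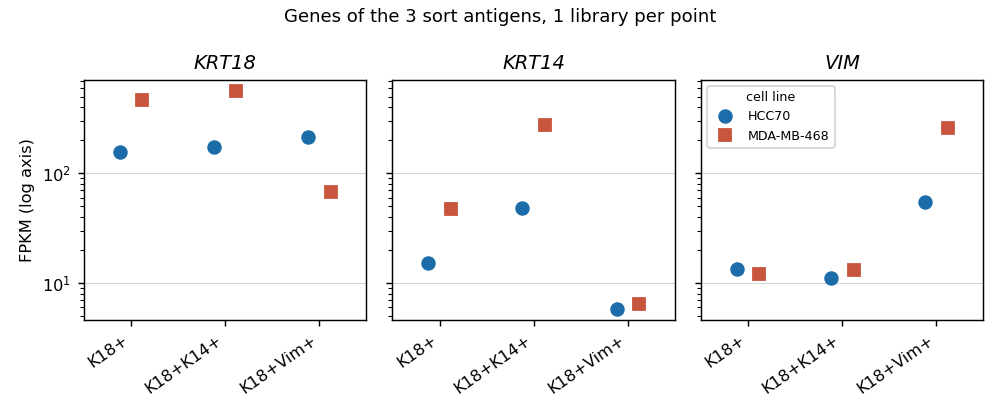
FPKM of KRT18, KRT14 and VIM on a log axis in the K18+, K18+K14+ and K18+Vim+ libraries, with 1 point per library, circles for HCC70 and squares for MDA-MB-468. KRT14 was highest in the K18+K14+ libraries, at 48.6 and 279 FPKM, and VIM in the K18+Vim+ libraries, at 54.8 and 259 FPKM.

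The comparison of K18+K14+ with K18+ cells asks which transcripts accompany keratin 14. Besides KRT14, several keratin and kallikrein genes had higher values in the K18+K14+ libraries of both lines, although no gene passed the test. KRT16 stood at 447 against 165 FPKM in HCC70 and at 160 against 49.8 FPKM in MDA-MB-468, and KRT6B at 39.2 against 14.5 and 19.6 against 2.89 FPKM. KRT4 was not among them, at 19.6 against 29.8 FPKM in MDA-MB-468. KRT17 stood at 92.7 against 38.0 FPKM in HCC70 and 677 against 219 FPKM in MDA-MB-468. The kallikrein proteases KLK8 and KLK10 were listed at 61.4 and 10.1 FPKM in the HCC70 K18+K14+ library, against 15.9 and 2.99 FPKM in the K18+ library. In MDA-MB-468 they were listed at 524 and 177 against 148 and 64.5 FPKM. SAA1, an acute-phase protein, stood at 20.4 against 6.25 FPKM and at 132 against 36.8 FPKM. Other genes with higher values in both lines were TPRN, which encodes the stereocilium protein taperin, with log2 ratios of 2.46 in HCC70 and 4.74 in MDA-MB-468, KIZ, a centrosomal protein gene, with 1.42 and 3.05, PPP1R1A with 1.82 and 2.11, PLEKHB1 with 1.57 and 1.95, and C5orf46 with 1.91 and 2.10.

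Lower values in the K18+K14+ libraries of both lines were found for the matrix protein gene FN1, which encodes fibronectin, at 10.3 against 50.1 FPKM in HCC70 and 6.11 against 25.2 FPKM in MDA-MB-468. NINL, a centrosomal protein gene, stood at 1.54 against 9.84 and 3.52 against 23.3 FPKM. CACYBP stood at 15.9 against 57.7 and 18.6 against 62.5 FPKM. The log2 ratios of TPST1, PPIP5K2, CCDC82, PCMTD2, BOD1L1 and MEGF6 lay between -2.10 and -1.48 in both lines. The readthrough transcript TGIF2-RAB5IF was listed at the floor of 0.1 FPKM in both K18+K14+ libraries and at 7.71 and 8.66 FPKM in the K18+ libraries. Its reads overlap those of its parent genes, so that value is uncertain.

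None of the 12454 genes passed an adjusted p of 0.05 in this comparison with limma, in which the cell line was a block. The smallest adjusted p was 0.855, and 428 genes had an unadjusted p under 0.05, or 3.44%. Simulated changes of log2 size 1 or 2 were recovered for 0 of 50 genes each, and of log2 size 4 for 42 of 50. The simulation used this size of design and the spread of the fit of all 6 libraries. That spread includes the library labelled MDA-MB-468 K18+Vim+, which is described below. With both, the test could reach only very large differences.

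Of 24 gene lists tested with camera at a preset correlation, 5 had higher and 1 lower values in K18+K14+ cells. All 6 calls ended with an estimated correlation, where each adjusted p = 0.928, and 0 lists passed with fry. Both were run only on all 6 libraries, with 2 residual degrees of freedom, and their power was not measured. Beside these lists, the MDA-MB-468 K18+K14+ library tilted towards short transcripts, with a Spearman correlation across genes of -0.303 between its log2 ratio to K18+ and transcript length, against -0.231 in HCC70. List medians are given relative to the median of all genes, which was -0.15 in HCC70 and -0.17 in MDA-MB-468. In the list of basal and myoepithelial genes 13 of 27 members were higher in both lines and 7 lower, with medians of 0.28 in HCC70 and 0.43 in MDA-MB-468 (camera adjusted p = 0.0195). KRT14 is itself a member. In the list of keratinocyte differentiation 9 of 17 were higher in both lines and 1 lower, with medians of 0.58 and 0.92 (camera adjusted p = 0.003), among them KLK8, KLK10, KLK6 and LCN2. Of 36 nuclear genes of oxidative phosphorylation 24 were higher in both lines and 0 lower, with medians of 0.23 in HCC70 and 1.22 in MDA-MB-468 (camera adjusted p = 9.99e-11), for example COX6B1 at 598 against 420 FPKM and 3314 against 982 FPKM. Of 73 ribosomal protein genes 30 were higher in both lines and 2 lower, with medians of 0.10 and 1.13 (camera adjusted p = 3.6e-12). RPLP2 stood at 1203 against 835 FPKM in HCC70 and 7758 against 1765 FPKM in MDA-MB-468. After quantile normalization the ribosomal protein list turned to the lower side, with a camera adjusted p of 0.844. Of 6 immune cell genes 4 were higher in both lines and 1 lower (camera adjusted p = 0.0289). One of the higher genes was CD14, at 138 against 90.0 FPKM in HCC70 and 50.7 against 28.3 FPKM in MDA-MB-468. CD14 is best known from monocytes. In the list of G2 and M phase genes 20 of 36 were lower in both lines and 5 higher, with medians of -0.03 and -0.56 (camera adjusted p = 0.0289). UBE2C was among the 5, at 128 against 87.0 FPKM in HCC70 and 348 against 188 FPKM in MDA-MB-468. CENPE, a kinetochore motor, stood at 1.64 against 3.91 and 0.695 against 10.4 FPKM. Without the MDA-MB-468 K18+K14+ library this list turned to the higher side (camera adjusted p = 0.605), and the basal (0.505), keratinocyte (0.461) and immune lists (0.263) no longer passed. They did not pass without HCC70 K18+ either (0.851, 0.851 and 0.376), nor did the immune list without HCC70 K18+K14+ (0.0517), nor the ribosomal (0.368) and G2 and M lists (0.271) without MDA-MB-468 K18+. After quantile normalization the oxidative phosphorylation (0.0776), basal (0.0884), keratinocyte (0.0801) and immune lists (0.0776) did not pass, and after length correction the keratinocyte (0.268) and immune lists (0.173) did not, nor did the immune list without the block for cell line (0.0549). In the fits without a K18+ or K18+K14+ library, the missing level is estimated through the line term. The library labelled MDA-MB-468 K18+Vim+ helps to set that term, so these list results are not those of the remaining pair alone. Without that library, which belongs to neither population compared here, the same 6 lists passed camera at the preset correlation in the same directions. Adjusted over the list alone, 0 genes passed in this comparison.

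The comparison of K18+Vim+ with K18+ cells asks which transcripts accompany vimentin, and here the library labelled MDA-MB-468 K18+Vim+ stood apart from the other libraries of its line. The Pearson correlation across genes of its log2 values with the MDA-MB-468 K18+ library was 0.828, against 0.919 between the K18+ and K18+K14+ libraries and 0.967 to 0.978 within HCC70. Genes that MDA-MB-468 is known to have lost or amplified differed in it. SMAD4 (Entrez Gene 4089), a transcription factor of TGF-beta signalling that is deleted in this line, was listed at 5.19 FPKM there and at 0.566 and 0.31 FPKM in the K18+ and K18+K14+ libraries. RB1 (Entrez Gene 5925), a deleted cell cycle inhibitor, was listed at 6.68 FPKM against 0.307 and 0.269 FPKM. EGFR (Entrez Gene 1956), a growth factor receptor amplified in this line, was listed at 10.4 FPKM against 153 and 70.7 FPKM. Its neighbours SEC61G, LANCL2 and VOPP1 stood at 720, 26.3 and 24.1 FPKM there and at 4875, 291 and 251 FPKM in the K18+ library. RB1 and these neighbours were singled out after the values were seen. In HCC70, SMAD4 ranged from 7.01 to 13.7 FPKM and EGFR from 11.2 to 23.3 FPKM. Below, MDA-MB-468 K18+Vim+ values are those of the library so labelled, and every direction drawn from it stands beside these values.

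**Figure D2:**
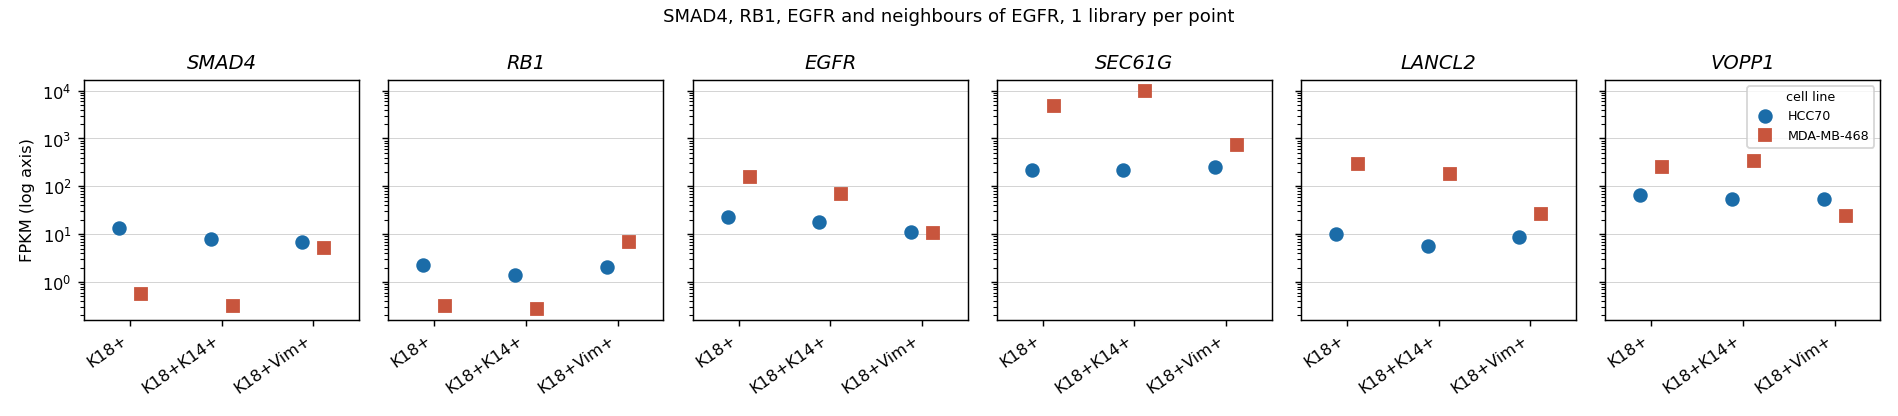
FPKM on a log axis of SMAD4, RB1, EGFR and the EGFR neighbours SEC61G, LANCL2 and VOPP1 in each library, with 1 point per library, circles for HCC70 and squares for MDA-MB-468. SMAD4 stood at 5.19 FPKM in the library labelled MDA-MB-468 K18+Vim+ and at 0.566 and 0.31 FPKM in the other libraries of that line.

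Of the genes with lower values in the K18+Vim+ libraries of both lines, ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, stood at 2.42 against 21.2 FPKM in HCC70 and 1.504 against 19.6 FPKM in the MDA-MB-468 libraries. PLA2G2A, a secreted phospholipase, stood at 98.6 against 628 and 1.99 against 22.1 FPKM. KRT4, a keratin of stratified mucosa, stood at 4.09 against 30.4 and 2.09 against 29.8 FPKM. The metalloproteinase gene MMP7 stood at 3.53 against 26.9 and 5.74 against 51.2 FPKM, and S100P at 214 against 863 and 4.57 against 38.6 FPKM. The log2 ratios of AQP3, TMEM156, SELENOP, IL20RA and ALCAM lay between -2.53 and -1.69 in both lines. Higher values in both lines were found, besides VIM, for the transcription factor gene BATF3 at 9.64 against 1.58 and 16.5 against 1.605 FPKM. LOXL1, a collagen cross-linking enzyme, stood at 11.2 against 2.37 and 8.16 against 1.90 FPKM, COL7A1 at 12.1 against 3.16 and 24.4 against 8.87 FPKM, and PCOLCE2 at 6.32 against 1.46 and 31.9 against 0.634 FPKM. BASP1, SLC22A17, ITGA2B and ANKRD18B had log2 ratios between 1.35 and 4.03. CALCB stood at 18.2 against 5.70 FPKM in HCC70 and at 12.7 FPKM against the floor of 0.1 FPKM in MDA-MB-468.

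No gene passed in this comparison. The smallest limma adjusted p was 0.863, and 532 genes had an unadjusted p under 0.05, or 4.27%. The count was also 0 without the library labelled MDA-MB-468 K18+Vim+. It was 1500 without the HCC70 K18+Vim+ library, a fit in which the library labelled MDA-MB-468 K18+Vim+ alone stood for the population.

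**Figure D3:**
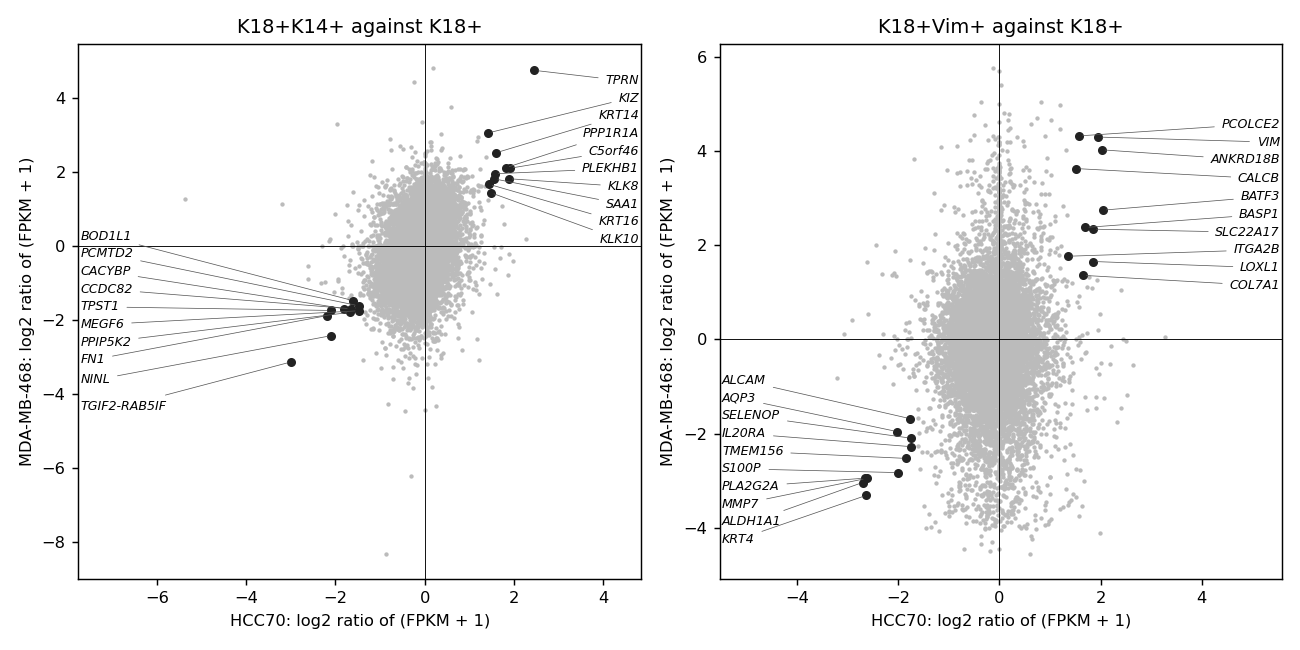
Log2 ratio of (FPKM + 1) of each of the 12454 genes tested, HCC70 on the x axis and MDA-MB-468 on the y axis, for K18+K14+ against K18+ on the left and K18+Vim+ against K18+ on the right. Grey points are all genes, and black points are the 10 named genes per direction, such as KRT14 at 1.61 and 2.52 on the left and VIM at 1.957 and 4.31 on the right.

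Of the 24 lists, 3 had higher and 7 lower values in K18+Vim+ cells, and most of the lower ones rested on the library labelled MDA-MB-468 K18+Vim+. All 10 calls, in this paragraph and the next, ended with an estimated correlation, with an adjusted p between 0.617 and 0.7, and 0 lists passed with fry. The mesenchymal list, of which VIM is a member, had 7 of 24 genes higher in both lines and 5 lower, with medians of 0.29 in HCC70 and 0.12 in MDA-MB-468 (camera adjusted p = 0.0437). COL6A1 stood at 2.02 against 0.218 and 31.2 against 0.985 FPKM, and COL5A1 at 21.9 against 8.08 FPKM in HCC70 and 1.605 against the floor of 0.1 FPKM in MDA-MB-468. Oxidative phosphorylation (medians 0.13 and 0.59, camera adjusted p = 0.000544) and ribosomal protein genes (0.09 and 1.15, camera adjusted p = 5.78e-11) were the other higher lists. Among the lower lists, genes of cholesterol synthesis were lower in both lines in 19 of 24 cases and higher in 0, with medians of -0.41 and -0.81 (camera adjusted p = 2.53e-06). The sterol enzymes MSMO1 and SC5D stood at 47.0 and 12.6 FPKM against 97.9 and 26.9 FPKM in HCC70, and at 19.3 and 20.1 FPKM against 40.4 and 40.7 FPKM in MDA-MB-468. The list of PDGF, FGF and EGF signalling had 21 of 26 genes lower in both lines and 1 higher, with medians of -0.08 and -0.92 (camera adjusted p = 3.93e-05). It holds EGFR.

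Lists of epithelial identity had medians near 0 in HCC70 and far below 0 in the MDA-MB-468 libraries. These were the luminal list (-0.05 and -2.60, camera adjusted p = 0.000225), basal and myoepithelial genes (0.00 and -1.77, camera adjusted p = 4.54e-06), epithelial junctions (-0.08 and -2.31, camera adjusted p = 9.44e-08) and keratinocyte differentiation (-0.11 and -3.45, camera adjusted p = 3.22e-07). EPCAM, an epithelial adhesion molecule, stood at 41.7 against 69.3 FPKM in HCC70 and 8.41 against 115 FPKM in MDA-MB-468. NF-kappaB and cytokine genes had medians of 0.16 and -0.62 (camera adjusted p = 0.0354). Without the library labelled MDA-MB-468 K18+Vim+, the mesenchymal (camera adjusted p = 0.021), oxidative phosphorylation (0.0128), ribosomal (0.00201) and cholesterol lists (0.00132) stayed under 0.05. Without it the G2 and M and the G1 and S lists also passed as lower, with HCC70 alone standing for K18+Vim+. Their medians in HCC70 were -0.18 and -0.31. In that fit the HCC70 level of K18+ is estimated from the MDA-MB-468 libraries as well, so the list results are not those of HCC70 alone. The luminal (0.665) and junction lists (0.991) turned to the higher side, and the basal (0.452), keratinocyte (0.409), NF-kappaB (0.665) and growth factor lists (0.317) no longer passed. Without MDA-MB-468 K18+, oxidative phosphorylation turned to the lower side (0.971), and the ribosomal (0.431) and NF-kappaB lists (0.293) did not pass. The mesenchymal list did not pass without HCC70 K18+ (0.119) or HCC70 K18+Vim+ (0.156), nor oxidative phosphorylation without HCC70 K18+Vim+ (0.116). The mesenchymal list also did not pass at a pseudocount of 0.1 (0.054) or 5 (0.0559), after quantile normalization (0.137) or after length correction (0.0517). Oxidative phosphorylation did not pass after quantile normalization (0.0736), nor the NF-kappaB list at a pseudocount of 5 (0.0515) or without the block for cell line (0.0534). Adjusted over the list alone, 4 genes passed: VIM, KRT4, KLK8 and ALDH1A1, of which VIM encodes an antigen used for the sort.

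**Figure D4:**
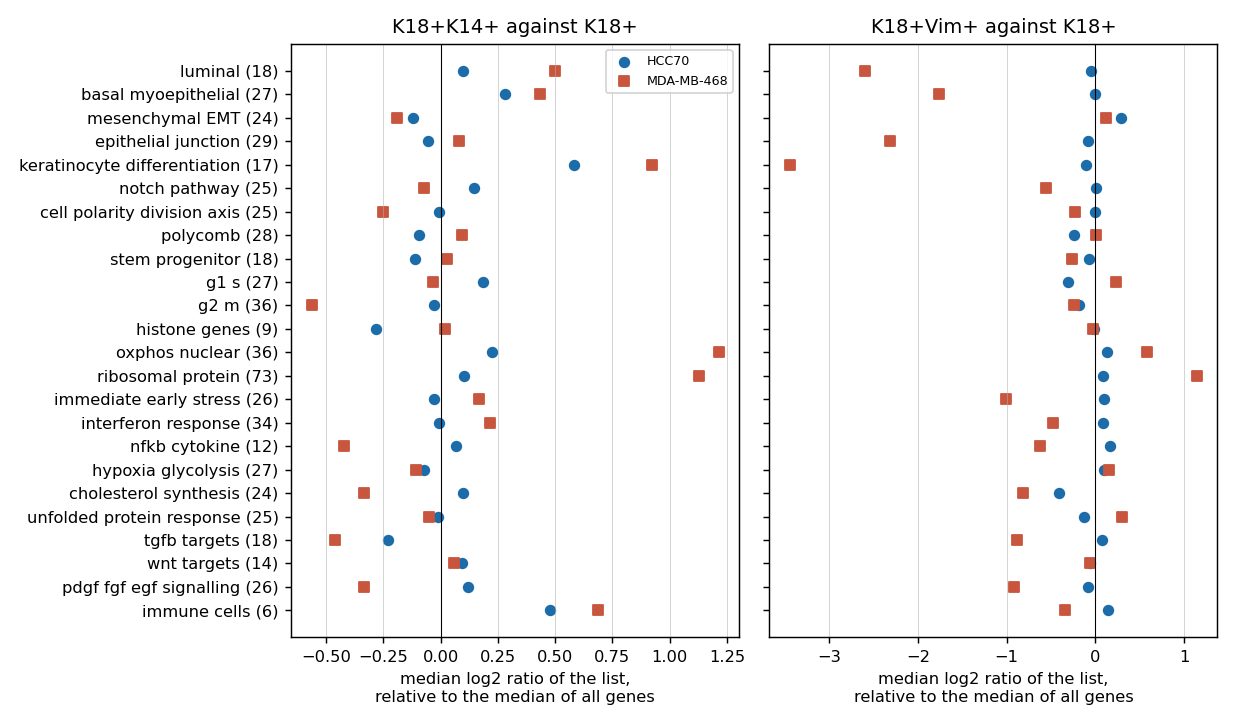
Median log2 ratio of each of the 24 gene lists relative to the median of all genes, with the number of genes tested in parentheses, circles for HCC70 and squares for MDA-MB-468, for K18+K14+ against K18+ on the left and K18+Vim+ against K18+ on the right. On the right the keratinocyte list lies at -0.11 in HCC70 and -3.45 in MDA-MB-468.

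The direct comparison of K18+Vim+ with K18+K14+ cells sets the vimentin and keratin 14 populations against each other. Lower values in K18+Vim+ cells of both lines were found for KLK8 at 5.02 against 61.4 FPKM in HCC70 and 11.9 against 524 FPKM in MDA-MB-468, for PI3, an elastase inhibitor, at 46.2 against 384 and 9.10 against 127 FPKM, and for MIA at 4.63 against 31.7 and 2.66 against 54.6 FPKM. PLA2G2A, PPP1R1B, KRT14, ALDH1A1, KRT4, MMP7 and SAA1 completed the 10 lower genes. Higher values were found for VIM, SAMD11 at 10.8 against 0.721 and 43.3 against 0.531 FPKM, MINDY3 at 29.1 against 6.13 and 22.5 against 3.64 FPKM, and ADNP2 at 14.1 against 2.74 and 8.85 against 1.504 FPKM, as well as SLC22A17, BASP1, ARL6, C12orf75, ATP8A1 and ADRA2C. Of 12454 genes 0 passed with limma, with a smallest adjusted p of 0.547 and 680 genes, or 5.46%, at an unadjusted p under 0.05. The count was 0 without the library labelled MDA-MB-468 K18+Vim+ and 1988 without the HCC70 K18+Vim+ library.

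Of the 24 lists, 1 was higher and 9 lower in K18+Vim+ than in K18+K14+ cells with camera at the preset correlation. All 10 calls ended with an estimated correlation, with an adjusted p between 0.618 and 0.789, and 0 lists passed with fry. The mesenchymal list was higher in K18+Vim+ cells (camera adjusted p = 0.0269), with 10 of 24 genes higher and 4 lower in both lines. FN1 was higher, at 81.6 against 10.3 FPKM in HCC70 and 16.9 against 6.11 FPKM in MDA-MB-468. Among the lower lists, keratinocyte differentiation (medians -0.38 and -4.48, camera adjusted p = 5.91e-11), basal and myoepithelial genes (-0.39 and -2.16, camera adjusted p = 9.25e-09), cholesterol synthesis (-0.57 and -0.41, camera adjusted p = 0.000224) and oxidative phosphorylation (-0.11 and -0.70, camera adjusted p = 0.0265) were lower in the median of both lines. They stayed under 0.05 without the library labelled MDA-MB-468 K18+Vim+, as did the mesenchymal list. In that fit too, the HCC70 level of K18+K14+ is estimated from the MDA-MB-468 libraries as well. The remaining lower lists were epithelial junctions (camera adjusted p = 1.79e-06), luminal genes (0.000118), PDGF, FGF and EGF signalling (0.000373), immune cells (0.0227) and interferon response (0.0395). Of these, the luminal (-0.168 and -3.09), growth factor (-0.245 and -1.16) and immune lists (-0.25 and -1.24) were also lower in the median of both lines. None of these 5 lists passed without the library labelled MDA-MB-468 K18+Vim+, where interferon response turned to the higher side. Oxidative phosphorylation turned to the higher side without the MDA-MB-468 K18+K14+ library (camera adjusted p = 0.865), and interferon response did not pass there (0.865). The mesenchymal list did not pass without HCC70 K18+K14+ (0.163) or HCC70 K18+Vim+ (0.126), nor oxidative phosphorylation without the latter (0.341). Oxidative phosphorylation also did not pass after quantile normalization (0.891), after length correction (0.332) or without the block for cell line (0.0538), nor interferon response after length correction (0.091) or at a pseudocount of 5 (0.0526), nor the immune list after length correction (0.0525). Without the library labelled MDA-MB-468 K18+Vim+ 3 further lists passed: hypoxia and glycolysis (0.0188) and TGF-beta (0.0111) as higher, and G1 and S (0.000548) as lower. Adjusted over the list alone, 19 genes passed, with 7 in the keratinocyte list, 5 in the basal list and 5 in the mesenchymal list. KRT14 was among the basal and VIM among the mesenchymal genes, and both encode antigens used for the sort. Of the 5 mesenchymal genes, S100A4 was lower, with a fitted log2 difference of -3.42.

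Lists close to the subject of the study, the choice between symmetric and asymmetric division, did not pass camera in any population comparison. In K18+K14+ against K18+ cells the adjusted p was 0.567 for cell polarity and division axis, 0.648 for the Notch pathway and 0.648 for polycomb genes. In K18+Vim+ against K18+ cells these were 0.766, 0.267 and 0.918, and in K18+Vim+ against K18+K14+ cells 0.51, 0.0706 and 0.588. Some single members had log2 ratios of the same sign in both lines. ITGB1, which encodes integrin beta 1, stood at 49.9 FPKM in K18+K14+ against 120 FPKM in K18+ cells of HCC70 and at 13.5 against 33.3 FPKM in MDA-MB-468, and DLG1 at 24.3 against 45.6 and 6.56 against 17.1 FPKM. ADAM10, the protease that cleaves Notch receptors, stood at 7.41 against 17.7 and 5.04 against 14.4 FPKM, whereas the Notch target HES4 stood at 747 against 422 and 348 against 142 FPKM. INSC, an adaptor of spindle orientation, stood at 3.21 against 1.06 FPKM in K18+Vim+ against K18+ cells of HCC70 and at 1.39 FPKM against the floor of 0.1 FPKM in MDA-MB-468. The other lists not passed in K18+K14+ against K18+ cells, which were stem cell, G1 and S phase, histone, immediate early and stress, interferon, NF-kappaB, hypoxia, cholesterol, unfolded protein, TGF-beta, Wnt, growth factor, luminal, mesenchymal and junction genes, had adjusted p-values between 0.468 and 0.967. In K18+Vim+ against K18+ cells the 14 lists not passed lay between 0.104 and 0.918, and in K18+Vim+ against K18+K14+ cells the 14 not passed lay between 0.0559 and 0.882. Of the list of fibroblast, endothelial and erythroid markers 3 genes were tested: COL1A1 ranged from 2.78 to 9.10 FPKM, FAP from 0.426 to 2.70 FPKM and ENG from 1.11 to 15.7 FPKM.

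Agreement between the lines was measured across genes, which are not independent replicates. The log2 ratios of K18+K14+ against K18+ in the 2 lines had a Pearson correlation of 0.321 and a Spearman correlation of 0.354, and 63.9% of genes had the same sign. At least 2-fold higher in both lines were 32 genes, against 8.76 if the lines were independent, and at least 2-fold lower were 92 against 45.0. The balance turned over with scaling, to 50 higher and 33 lower after quantile normalization and 49 higher and 38 lower after length correction. For K18+Vim+ against K18+ the Pearson correlation was 0.040 and the same-sign share 50.4%, with 47 genes higher against 23.8 and 89 lower against 72.1. At least 2-fold in opposite directions were 95 genes against 84.2 here, and 27 against 41.4 in K18+K14+ against K18+. The balance of higher and lower genes turned over here too. It became 70 higher and 52 lower after quantile normalization and 74 higher and 52 lower after length correction. For K18+Vim+ against K18+K14+ the Pearson correlation was 0.046 and the same-sign share 49.4%. In the last 2 comparisons 1 of the libraries was the one labelled MDA-MB-468 K18+Vim+.

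The lines themselves were compared over the 3 populations, with population as a term. The 3 libraries of a line are 3 sorted populations of it, not separate cultures. The SD and p-values of this comparison therefore do not measure the spread between cultures of a line. Limma gave 565 genes higher and 957 lower in MDA-MB-468 at an adjusted p under 0.05. Of these 1522 genes, 1504 had libraries of the lines that did not overlap. Among all genes tested 41.2% did not overlap, against 10% by chance for 3 libraries against 3. Of the interferon response list, 19 of 34 genes were lower in MDA-MB-468 and 0 higher, and 26 passed adjusted over the list alone. IFI27 stood at 949 ± 259 FPKM (SD, n = 3) in HCC70 and 3.42 ± 4.83 FPKM in MDA-MB-468, with a log2 difference of -8.28 ± 0.50 (SE, limma adjusted p = 0.00144). The MDA-MB-468 mean of IFI27 is carried by the library labelled K18+Vim+, at 9.001 FPKM, against 0.769 FPKM in K18+ and 0.491 FPKM in K18+K14+. BST2, which encodes tetherin, stood at 306 ± 45.2 against 4.12 ± 2.39 FPKM, and IFITM1 at 210 ± 44.1 against 3.91 ± 2.38 FPKM. Also lower in MDA-MB-468 were WFDC2 at 356 ± 15.5 against 4.11 ± 1.15 FPKM, TCN1, a vitamin B12 binder, at 304 ± 68.3 against 1.65 ± 1.54 FPKM, and CXCL17 at 397 ± 227 against 1.05 ± 0.27 FPKM. DMBT1 stood at 135 ± 36.0 FPKM in HCC70 and at the floor of 0.1 FPKM in every MDA-MB-468 library. SMIM22, CRIP1, CD74, KLHDC7B and GABRE completed the 10 lower genes, with log2 differences between -7.82 and -6.06.

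Higher in MDA-MB-468 were S100A7, which encodes psoriasin, at 1460 ± 1518 against 2.04 ± 0.68 FPKM (SD, n = 3), CYBA, a subunit of the NADPH oxidase, at 701 ± 432 against 6.13 ± 4.89 FPKM, and TUSC3 at 48.3 ± 4.56 against 0.547 ± 0.356 FPKM. PCSK1N was listed at the floor of 0.1 FPKM in every HCC70 library and at 29.7 ± 18.1 FPKM in MDA-MB-468. WNT6, MYEOV, PRODH, LDHB, CLDN10 and CRISP3 were also higher, with log2 differences between 4.52 and 5.31. In the library labelled MDA-MB-468 K18+Vim+, S100A7 stood at 90.9 FPKM. WNT6, MYEOV, PRODH, CLDN10 and CRISP3 stood between 4.78 and 6.82 FPKM there, each below both other MDA-MB-468 libraries. LDHB at 810 FPKM and PCSK1N at 48.1 FPKM stood above both. By list, 8 of 27 basal genes, 5 of 9 histone genes and 5 of 12 NF-kappaB genes were lower in MDA-MB-468 and 0 higher. Of 25 Notch pathway genes 8 were lower and 3 higher, and of 24 mesenchymal genes 4 were lower and 1 higher. Of 17 keratinocyte genes 5 were higher and 1 lower, and 8 of 73 ribosomal protein and 6 of 36 oxidative phosphorylation genes were higher with 0 lower. Among 28 polycomb genes 0 passed. The count of 1522 moved with each library left out: it was 206 without HCC70 K18+, 288 without HCC70 K18+K14+, 3360 without HCC70 K18+Vim+, 241 without MDA-MB-468 K18+, 326 without MDA-MB-468 K18+K14+ and 3344 without the library labelled MDA-MB-468 K18+Vim+. When a library is left out, the other library of its population is fitted by its own population term. The counts without either library of a population therefore both rest on the pairs of the other populations. With no filter on low values the count of genes was 15.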

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

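The tests of EGFR and its neighbours and of genes found in HCC70 were chosen after the result was seen. The length correction was added after the data were seen, with its bounds set before its result.

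Among the 3 sort antigens and the lists that passed camera with the preset correlation, the lines went opposite ways in 6 cases, each with 1 library per line and population, so that the differences were not tested. VIM in K18+K14+ against K18+ differed by 0.36 between the lines on the log2 scale, with -0.25 in HCC70 and 0.12 in MDA-MB-468. The other 5 involve the library labelled MDA-MB-468 K18+Vim+. KRT18 differed by -3.21 in K18+Vim+ against K18+ and by -3.36 in K18+Vim+ against K18+K14+. The medians of the NF-kappaB list differed by -0.79 in K18+Vim+ against K18+, and those of the junction list by -2.55 and the interferon list by -0.77 in K18+Vim+ against K18+K14+.

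The library labelled MDA-MB-468 K18+Vim+ stood apart from its line. K18+K14+ differed from K18+ by more than 4-fold in 291 genes in MDA-MB-468 and in 17 genes in HCC70. In the library labelled MDA-MB-468 K18+Vim+, 1129 genes differed from K18+ by more than 4-fold, against 40 for the same comparison in HCC70. Transcript length bias is argued against, since 94.5% of those genes with a length stayed beyond 4-fold after a length correction. HCC70 RNA as the whole source is argued against too: 29 genes at 10 FPKM or more in every HCC70 library and at 0.3 FPKM or less in the other MDA-MB-468 libraries stood there at a median of 1.31% of their HCC70 mean, although 12 of them reached 1 FPKM, whereas SMAD4 stood at 54.3% of its HCC70 mean. Cells other than MDA-MB-468 in that library, or a wrong label, remain a candidate explanation. EGFR and 3 neighbours had a median log2 ratio of -3.37 to K18+. RB1, also deleted in this line, was listed at 6.68 FPKM there, against 0.307 FPKM in K18+ and 0.269 FPKM in K18+K14+. It was singled out after the values were seen. SMAD4 at 5.19 FPKM stayed undecided. The prediction asked for under 0.5 FPKM in both other libraries, and K18+ held 0.566 FPKM. The line profile over gene windows had a slope of 0.577 (95% interval 0.475 to 0.68), between the bounds of 0.5 and 0.8, against 0.94 for K18+K14+. A difference between vimentin-positive and other MDA-MB-468 cells stays open and untested, since 1 library carries both the population and any foreign RNA.

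Ribosomal protein genes were listed higher in the MDA-MB-468 K18+K14+ library than in K18+, with a median log2 ratio of 1.13 relative to all genes, against 0.10 in HCC70. The median was 0.83 after the length correction, above the bound of 0.5. This argues against transcript length bias as the whole cause only as far as the lengths used hold. They were those of the longest transcript of each gene, which can be longer than the one expressed. The list turned to the lower side after quantile normalization (camera adjusted p = 0.844), so the scaling of a library in which 100 genes take 36.3% of the summed FPKM remains open, and the population difference stays untested with 1 library.

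The count of genes that differ between the lines was 1875 in a fit of cell line alone. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 with as many genes, and the highest other split gave 0.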

How the results depend on the processing

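The length correction was added after the data were seen. The fit with no replicate block (population or cell line only) gave 0 genes for each pair of populations and 1875 genes for the lines, and the blocked and unblocked fits differed in no count of calls by over 1.5 times. Without the block, the immune list in K18+K14+ against K18+ (0.0549), the NF-kappaB list in K18+Vim+ against K18+ (0.0534) and oxidative phosphorylation in K18+Vim+ against K18+K14+ (0.0538) did not pass. The cause of the shifts below was not tested unless stated. Over all settings, counts of genes changed stayed within 1.5 times in 48 cases and moved in 11. With each library left out in turn, they ranged from 0 to 1 (K18+K14+ against K18+), 0 to 1500 (K18+Vim+ against K18+), 0 to 1988 (K18+Vim+ against K18+K14+) and 206 to 3360 (lines). The 1 gene each came without HCC70 K18+K14+. Without a filter the lines differed in 15 genes. Lists passed were 0 in all 3 comparisons with an estimated correlation and with fry, 1 after quantile normalization in K18+K14+ against K18+, and 5 to 8, 6 to 10 and 8 to 13 with libraries left out. The Pearson correlation of the lines for K18+K14+ against K18+ moved to 0.262 (pseudocount 0.1), 0.364 (pseudocount 5), 0.363 (minimum 5 FPKM), 0.278 (length correction) and 0.354 (Spearman), and for K18+Vim+ against K18+K14+ to 0.018 (Spearman). In K18+K14+ against K18+, KRT18 turned to -0.15 and VIM to 0.19 after quantile normalization, VIM to 0.033 and COX8A to -0.015 after length correction, and the ribosomal list to the lower side (0.844) after quantile normalization. With libraries left out in turn, log2 differences in K18+K14+ against K18+ ranged from -0.66 to 1.09 (KRT18), -0.745 to 0.611 (VIM), -0.158 to 1.59 (LCN2), -0.111 to 0.745 (ATP5MC1) and -0.197 to 1.002 (ITGB2). In fits without a K18+ or K18+K14+ library, the missing level was estimated through the line term. The library labelled MDA-MB-468 K18+Vim+ helps to set that term. KRT18 (log2 ratios 0.141 in HCC70 and 0.293 in MDA-MB-468), LCN2, ATP5MC1 and ITGB2 were higher in both lines. Their negative values therefore came from neither pair, whereas VIM went opposite ways in the pairs. In K18+Vim+ against K18+ the log2 differences ranged from -2.94 to -1.04 (KRT14), -2.80 to 0.484 (KRT18), 2.05 to 4.21 (VIM) and -0.051 to 0.704 (NDUFS8), and in K18+Vim+ against K18+K14+ from -5.01 to -3.10 (KRT14), -3.01 to 0.267 (KRT18) and 2.11 to 4.28 (VIM). The sort marker genes passed in both of these comparisons only without HCC70 K18+Vim+, a fit with MDA-MB-468 alone in that population, so that 1 sample is assumed to vary like the others. Camera adjusted p-values ranged from 0.000109 to 0.605 (G2 and M, K18+K14+ against K18+), 3.57e-07 to 0.665 (luminal), 1.19e-12 to 0.991 (junction) and 3.4e-07 to 0.971 (oxidative phosphorylation) in K18+Vim+ against K18+, and 0.00213 to 0.865 (oxidative phosphorylation) and 0.00437 to 0.874 (interferon) in K18+Vim+ against K18+K14+. The unknown depth sets no counting limit here.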

Other observations

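The values below are of genes and lists that the report describes only in part, and no test was added for them.

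In the HCC70 libraries alone, 96 genes stood at least 2-fold higher and 290 lower in K18+K14+ than in K18+, and 205 higher and 426 lower in K18+Vim+ than in K18+. The balance depends on scaling: after quantile normalization the counts were 154 higher and 128 lower, and 318 higher and 233 lower, and after length correction 155 and 138, and 330 and 222. With 1 library each these are values without a test. The hypoxia and glycolysis list had medians of 0.32 in HCC70 and 0.44 in MDA-MB-468 in K18+Vim+ against K18+K14+ (camera adjusted p = 0.0569, and 0.0188 without the library labelled MDA-MB-468 K18+Vim+), with BNIP3 at 3.69 against 0.992 and 7.24 against 1.92 FPKM, and P4HA1, a collagen hydroxylase, at 7.53 against 3.51 and 8.56 against 3.36 FPKM. In the TGF-beta list 6 of 18 members had higher values and 1 lower in K18+Vim+ than in K18+K14+ cells of both lines, among the 6 TGFB1 at 27.3 against 9.87 and 24.1 against 8.49 FPKM and ID3 at 233 against 115 and 98.2 against 53.8 FPKM. Against K18+ cells TGFB1 was not higher in both lines, at 27.3 against 16.9 FPKM in HCC70 and 24.1 against 46.6 FPKM in MDA-MB-468. The list as a whole did not pass against K18+K14+ (camera adjusted p = 0.882, and 0.0111 as higher without the library labelled MDA-MB-468 K18+Vim+), with a median fitted difference of -0.33 relative to all genes while camera's direction was higher.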
